A study of Mus musculus with 38 samples.

How the data were processed

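RNA-seq had been run on live, lineage-negative mammary tumour cells sorted by Confetti marker and by CD24, 38 libraries in all. Per the labels, RNA was isolated with the miRNeasy Micro kit, 8 libraries (tumour K5) were prepared with the Clontech SMART-Seq v4 kit and 30 with the TruSeq kit, and sequencing fell on 5 dates. The deposited values are read counts per gene and per exon, whole numbers with no normalization, made by the authors with featureCounts on mm10 per the submitters' processing notes. The authors' gene table gives gene lengths in bases, which were not used in the tests. The aligner, the strand setting, the annotation version, read filters and tool versions are not given in the sources used here. The count tables held 27179 genes and 222996 exons. The 38 deposited single-library files were identical to the matching columns of the gene table, and 0 value columns were left without a sample.

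Entrez gene identifiers were matched to symbols through a RefSeq gene table, and gene positions were taken from the authors' exon table. GENCODE vM21 on GRCm38, the assembly of mm10, served for the annotation of exons and the GC content of genes. Of the identifiers, 25275 matched a symbol and 1904, with 1.21% of counts, did not. Reads of close paralogs are uncertain, since how multi-mapped reads were treated is not given in the sources used here. Library totals ran from 15363 to 79739562 counts, and 4 libraries fell under 2000000. The highest correlation between 2 libraries of a group was 0.987. The CD24- sum of each tumour correlated most with the CD24+ sum of the same tumour in all 8 tumours, at 0.424 to 0.725 (in tumour E6 against 0.414 for the next), after the mean profile of each CD24 state was removed.

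Groups were K5-rtTA and Elf5-rtTA, each CD24+ and CD24-. Clones of 1 tumour are not independent, so counts were summed per tumour and CD24 state into 16 sums, and the tumour was the replicate. In the 5 tumours with more than 1 clone the sums weight clones by depth, and the weights differ between fractions. The RFP clone of K2 gave 34320816 of 35825373 CD24- counts but 22608083 of 56945977 CD24+ counts. The RFP clone of E3 gave 24634341 of 43833705 and 7954197 of 73801677. The CD24 and driver contrasts can therefore mix clone composition with CD24 state or driver. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR's robust quasi-likelihood F-test, with Benjamini-Hochberg adjustment at 0.05. CD24- was compared with CD24+ with tumour as a block (n = 8). The drivers were compared within each CD24 state (3 tumours against 5) with no batch term. The interaction of driver and CD24 was tested with tumour as a block. A model of all 38 libraries with clone and tumour-by-CD24 terms (residual degrees of freedom 11, common biological coefficient of variation 0.653) tested whether the CD24 effect differed among tumours, whether clones of a tumour differed, and the CD24 effect within each of the 5 tumours with more than 1 clone. Exon counts were tested with diffSpliceDGE and Simes p-values per gene. All these tests are two-sided. Log2 CPM used a prior count of 2, and fold changes are those of the fit.

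Gene lists covered epithelial, mesenchymal, EMT transcription factor, basal, luminal progenitor, mature luminal, proliferation, p53 target, TGF-beta target, hypoxia, interferon, Wnt target, immediate early and mitochondrially encoded genes, markers of macrophages, T and NK cells, B cells, neutrophils, endothelial cells, pericytes, fibroblasts, erythroid cells, adipocytes, Schwann cells and skeletal muscle, and exon targets of epithelial splicing regulators. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists with fewer than 3 tested genes were not tested. Members counted as tested are those expressed above the filter in these cells.

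Genes were named by a fixed rule. Cd24a, Trp53, Pten, Krt5 and Elf5 were always named. For the CD24 contrast the rule took the 12 largest changes in each direction among called genes with a mean log2 CPM of at least 3 and 1 direction in all 8 tumours. For the drivers it took the 8 largest in each direction, or the 3 smallest p-values where none was called. It took the 6 smallest p-values for differences among tumours, 3 per tumour for clones, the 6 smallest Simes p-values and called splicing-list members for exons, up to 4 members of each list, and 10 canonical EMT and keratin genes. Predicted genes were passed over. Genes outside the rule are said to have been named after their values were seen.

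The share of Trp53 and Pten exon reads in each exon was computed per library and per tumour with Wilson 95% intervals. Which exons are floxed is background knowledge of the commonly used alleles. Reads per base in the floxed exons were also divided by those in the flanking exons.

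Alternatives were RLE scaling, DESeq2 in place of edgeR for the tumour sums, limma-voom in place of edgeR for the clone model, limma-voom with single libraries as replicates and tumour as a random block for the drivers, no filter on low counts, clones weighted equally, no replicate block, clones as blocks, date as a block, K4 GFP left out, and each tumour or clone left out in turn. For exon usage they were limma's diffSplice, a stricter filter and clones as blocks. Exon counts summed per gene and the omission of clones with a library under 2000000 counts were added after the data were seen. All models were tested on simulated negative binomial counts of the same design and depth. Changes were planted in well-expressed genes, for gene counts those with a mean log2 CPM of at least 3. In the clone model no other CD24 effect was simulated. Recovery in genes of lower expression is therefore not known. For CD24- against CD24+, 68 of 100 genes changed 2-fold and 98 of 100 changed 4-fold were recovered. For the drivers the changes simulated were raised to 4-fold and 32-fold after a first run with smaller ones recovered 0. In CD24+ cells 41 and 95 of 100 were then recovered, and in CD24- cells 24 and 91. For the interaction, 0 of 100 genes changed 2-fold and 26 of 100 changed 4-fold were recovered, and for differences among tumours 0 of 100 changed 4-fold and 21 of 100 changed 16-fold. For clone differences, simulated in tumour K5, 5 of 100 genes changed 4-fold and 47 of 100 changed 16-fold were recovered. For exon usage 19 of 100 exons changed 2-fold and 92 of 100 changed 4-fold were recovered.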

Results

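Gene and exon read counts were measured by RNA-seq in 38 libraries from 8 mouse mammary tumours. Live cells negative for lineage markers had been sorted by Confetti colour, a fluorescent mark that Cre sets and daughter cells inherit, and by the surface protein CD24. The cells of 1 colour in a tumour are taken as a clone, as in the series design. Each of 19 clones gave a CD24+ and a CD24- library. Cre had been switched on by a reverse tetracycline transactivator driven by the promoter of Krt5, a keratin of basal cells (K5-rtTA, tumours K2, K4 and K5), or of Elf5, a transcription factor of luminal progenitors (Elf5-rtTA, tumours E1, E2, E3, E5 and E6). The K5-rtTA groups held 11 libraries in each CD24 state from 3 tumours, and the Elf5-rtTA groups held 8 from 5 tumours. Library totals ran from 15363 counts (the GFP CD24- library of tumour K4) to 79739562, and 4 CD24- libraries had fewer than 2000000. Summed over the clones of a tumour, each CD24 state had 20149326 to 79739562 counts. The labels do not say whether the tumours came from separate mice, so the p-values measure the spread between these tumours. Intervals and floors cover counting error only, since the reads carried no molecular identifiers. Positions are on mm10.

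The strain labels give homozygous floxed alleles of Trp53, the tumour suppressor p53, and of Pten, the phosphatase that opposes PI3K signalling, whereas the series design text names a progestin and a carcinogen and no floxed gene. The exon counts addressed whether the floxed exons were missing from the transcripts. Exons 2 to 10 of Trp53 (chr11:69586891-69590762), the part removed in the commonly used floxed allele, held 108 of 4436 Trp53 exon reads, 2.43% (Wilson 95% interval 2.02 to 2.93), although they make up 58.4% of the exon length. Trp53 exon 11 (chr11:69591254-69591873), after the removed part, held 3686 reads and exon 1 held 642. Exon 5 of Pten (chr19:32799861-32800099), removed in the commonly used floxed allele, held 15 of 97096 Pten exon reads, 0.02% (Wilson 0.01 to 0.03), against 2.9% of the exon length, and 6 of 92193 without the CD24- library of tumour E2. The Trp53 share was 1.75% in CD24+ cells (50 of 2853, Wilson 1.33 to 2.30) and 3.66% in CD24- cells (58 of 1583, Wilson 2.84 to 4.71). Single libraries carried much of it: without the CFP CD24+ library of K5 the CD24+ share was 0.63% (17 of 2713, Wilson 0.39 to 1.0), and without that of tumour E2 the CD24- share was 2.28% (32 of 1405, Wilson 1.62 to 3.20). Of the 35 libraries with any Trp53 exon reads, 19 had none in the removed part, and 31 of 38 libraries had none in Pten exon 5. The labels do not name the floxed exons. The remaining reads were uneven: reads per base in the removed Trp53 part, as a percentage of those in the flanking exons, were 12.18% in the CD24- cells of tumour E2, 8.60% in those of E3 (7 of 65 reads, all 7 in the YFP clone at 18.46%) and 4.65% in those of K5 (GFP clone 15.96%). They were 5.60% in the CD24+ cells of K5, where the CFP clone had 21.96%, and at most 2.31% in the other tumour sums.

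**Figure D1:**
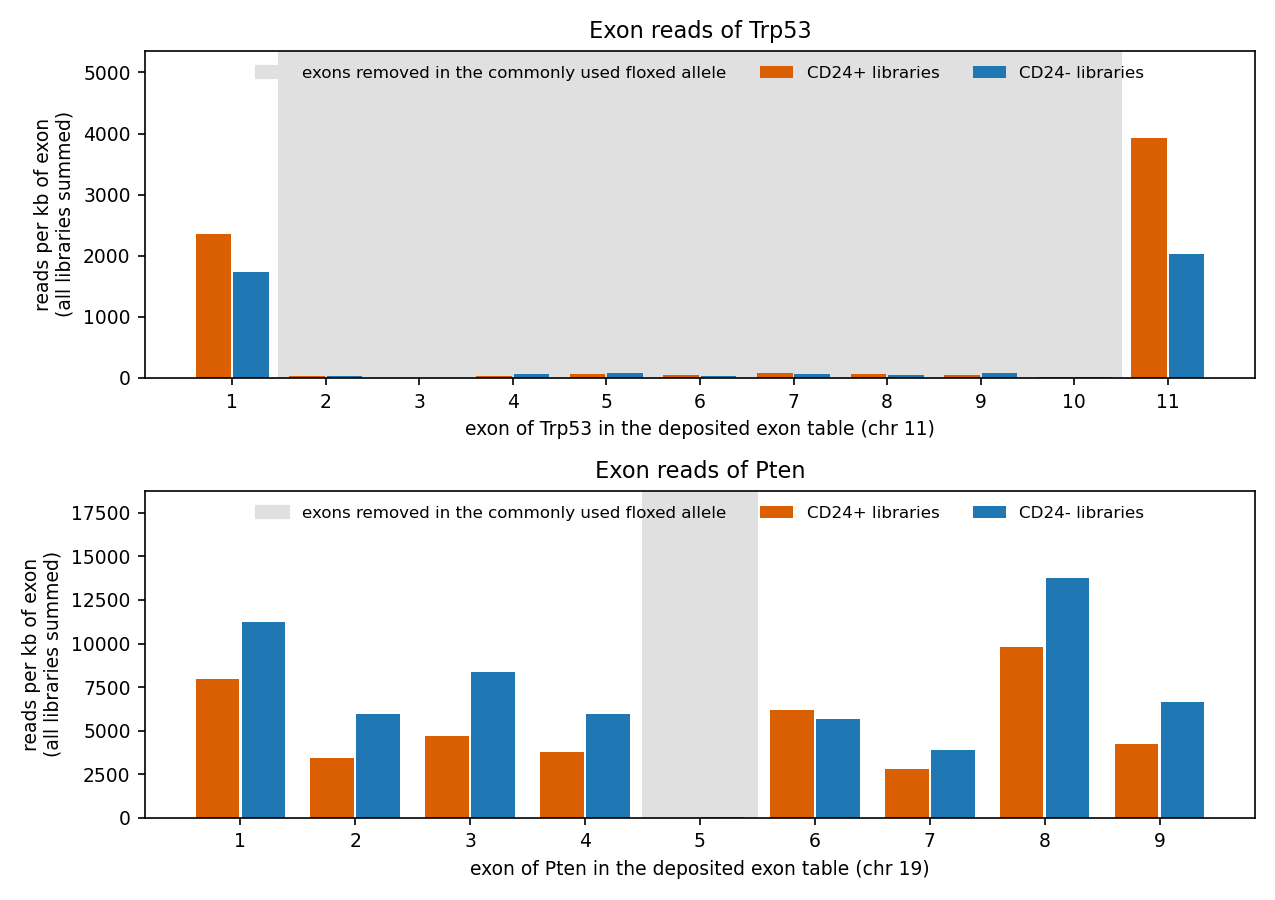
Reads per kilobase in each exon of Trp53 and Pten, all libraries of a CD24 state summed (orange CD24+, blue CD24-), with the exons removed in the commonly used floxed alleles shaded grey. Trp53 exons 2 to 10 held 108 of 4436 reads and Pten exon 5 held 15 of 97096.

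CD24 is a surface protein of mammary epithelial cells, and the sort asked how the CD24- cells of a tumour differed from the CD24+ cells of the same tumour. The mean level of the epithelial list of adhesion, polarity and keratin genes was lower in the CD24- cells of all 8 tumours, and that of the mesenchymal list was higher in 7 of 8, all but E5. Cd24a (chr10:43579169-43584265), the gene of the sorted protein, stood at 16.5 ± 17.9 CPM (counts scaled by library size, SD, n = 8 tumours) in CD24- cells against 486 ± 270 in CD24+ cells, a log2 ratio of -5.35 (SE 0.50, adjusted p = 0.000396, lower in all 8 tumours). Cldn4 (chr5:134945123-134946934), a tight junction protein, fell by 6.29 on the log2 scale (SE 0.63, adjusted p = 0.00057), from 403 ± 418 to 4.82 ± 4.41 CPM. Fap (chr2:62500945-62574021), a protease of activated fibroblasts, rose by 3.62 (SE 0.47, adjusted p = 0.00146), from 9.58 ± 8.43 to 148 ± 136 CPM.

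Among the most lowered genes, each lower in all 8 tumours, were Clic6, a chloride channel protein (-7.03, SE 0.58, adjusted p = 0.000224, chr16:92498147-92541241), the mucin Muc15 (-6.97), the apical polarity gene Crb3 (-6.84), the proton pump subunit Atp6v1b1 (-6.69) and the secreted glycoprotein Dmbt1 (-6.38). The membrane protease Tmprss13 (-6.36), the tight junction gene Cldn7 (-6.27), the cornified envelope gene Sprr2a3 (-6.26), the recycling GTPase Rab25 (-6.19), beta-casein Csn2 (-6.19) and the surface antigen Ly6d (-6.16) completed that set. Sprr2a3 has close copies that counts cannot fully separate. The most raised genes, higher in all 8 tumours, included the laminin Lama2 (4.32, SE 0.54, adjusted p = 0.00134, chr10:26981285-27616942), the collagens Col15a1 (3.85, SE 0.43, adjusted p = 0.000843, chr4:47208012-47313165), Col6a5 (3.69) and Col10a1 (3.67), the sodium pump subunit Atp1a3 (4.05) and Apold1 (3.93), an endothelial early response gene. The others were the Notch target Heyl (3.73), the microRNA host Dnm3os (3.58), the collagen receptor Ddr2 (3.48), the pericyte and fibroblast surface protein Cd248 (3.48) and the branched-chain aminotransferase Bcat1 (3.42). Their adjusted p-values lay at or below 0.00681.

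The genes of the drivers and of the epithelial-mesenchymal transition (EMT) moved as follows. Elf5 (chr2:103412098-103450989) fell by 5.65 (SE 0.56, adjusted p = 0.00054) and Krt5 (chr15:101707070-101712891) by 4.72 (SE 0.94, adjusted p = 0.00606), each in 8 of 8 tumours. Epcam, an epithelial adhesion protein, fell by 5.36 and E-cadherin, Cdh1, by 4.74. The basal keratin Krt14 fell by 3.80 and the basal transcription factor Trp63 by 2.94, the latter in 7 of 8 tumours. The intermediate filament gene Vim rose by 1.84, and the EMT repressors Zeb2, Zeb1 and Twist1 by 2.45, 2.19 and 1.41, in all 8 tumours. Snai2 (0.98) and Snai1 (0.52, adjusted p = 0.0463) rose too, each higher in 6 of 8 tumours. Pten (chr19:32757577-32826160) was 260 ± 154 CPM in CD24- and 114 ± 73.3 in CD24+ cells, a rise of 1.18 (SE 0.24, adjusted p = 0.00626, 7 of 8 tumours). Trp53 (chr11:69580359-69591873) had a log2 ratio of -0.18 (SE 0.21, adjusted p = 0.540).

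Of the epithelial list of adhesion, polarity and keratin genes, 36 of 36 tested members fell over all genes and 36 adjusted over the list alone (camera adjusted p = 2.2e-23, but adjusted p = 0.312 with an estimated correlation), Mal2 by 6.05. Of the mesenchymal list of matrix and cytoskeleton genes, 32 of 33 rose, and 32 adjusted over the list alone (camera adjusted p = 1.8e-16, adjusted p = 0.312 with an estimated correlation), with Cdh11 at 3.65, Col1a1 at 3.60 and Thy1 at 3.59. Of 11 EMT transcription factors 9 rose, and 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.000773, adjusted p = 0.312 with an estimated correlation), among them Twist2 (3.06) and Prrx1 (3.02). Of 19 luminal progenitor genes 15 fell, and adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 4.7e-10, adjusted p = 0.312 with an estimated correlation), including the epithelial factor Ehf (-5.99), lactoferrin Ltf (-5.78) and Wfdc18 (-5.71). Of 12 mature luminal genes 8 fell, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000179, adjusted p = 0.312 with an estimated correlation), including the progesterone receptor Pgr (-6.03), the prolactin receptor Prlr (-5.48), Foxa1 (-4.67) and Cited1 (-3.93). The basal list split, with 4 of 20 members higher and 11 lower, and 6 and 13 adjusted over the list alone (camera adjusted p = 0.0665), with Krt15 at -4.89 and Krt17 at -3.58. The 4 higher ones, named after their values were seen, were the contractile genes Tagln (1.97), Cnn1 (1.40) and Mylk (1.40) and the collagen Col7a1 (1.86).

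Markers of stromal cells moved with the mesenchymal genes. Of 10 fibroblast markers 8 rose, and 8 adjusted over the list alone (camera adjusted p = 0.000519, adjusted p = 0.312 with an estimated correlation), with the matrix genes Lum (3.77), Smoc2 (2.98), Mfap5 (2.95) and Dpt (2.85). Of 6 pericyte markers 5 rose, and 5 adjusted over the list alone (camera adjusted p = 0.00334, adjusted p = 0.312 with an estimated correlation), with Abcc9 (3.27), the PDGF receptor Pdgfrb (3.25) and Rgs5 (3.20). Of 12 endothelial markers 3 rose, and 4 adjusted over the list alone (camera adjusted p = 0.0156, adjusted p = 0.538 with an estimated correlation), namely Esam (2.58), Plvap (2.33) and Egfl7 (1.39) over all genes. Macrophage markers gave 0 of 15 higher and 1 lower, and 0 and 1 adjusted over the list alone (camera adjusted p = 0.997, mean -0.04, median 0.11), the lower one being the antigen presentation gene H2-Ab1 (-1.41). Of 3 erythroid genes 2 were lower, and 2 adjusted over the list alone (camera adjusted p = 0.0668), the globins Hba-a1 (-2.70) and Hba-a2 (-2.26), whose reads cannot be fully told apart. Of 4 Schwann cell genes 1 was lower, and 1 adjusted over the list alone (camera adjusted p = 0.506), the myelin gene Mbp (-4.68). The T and NK cell, B cell, neutrophil, adipocyte and skeletal muscle lists had fewer than 3 tested genes. Apart from a few splicing targets, no gene stood on more than 1 list.

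Among pathway lists, 8 of 18 TGF-beta targets rose and 1 fell, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.00183, adjusted p = 0.312 with an estimated correlation), led by the basement membrane collagens Col4a1 (2.74) and Col4a2 (2.65), with Ltbp2 (1.49) and Tgfb2 (1.46). Of 28 proliferation genes 6 fell, and 6 adjusted over the list alone (camera adjusted p = 0.00249, adjusted p = 0.538 with an estimated correlation), with Mki67 at -0.79, Nusap1 at -0.78, Kif11 at -0.71 and Pcna at -0.50. Of 13 mitochondrially encoded genes 2 fell over all genes, COX2 (-0.72) and ATP6 (-0.65), and 0 adjusted over the list alone (camera adjusted p = 0.00195, adjusted p = 0.538 with an estimated correlation). Wnt targets had 5 of 12 higher, and 5 adjusted over the list alone (camera adjusted p = 0.157), including Sp5 (2.43), Apcdd1 (2.27), Nkd1 (1.68) and Axin2 (1.15). Of 22 p53 targets 4 were higher and 2 lower, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.373, mean -0.08, median 0.19), with Perp at -2.97, Trp53inp1 at -2.85, Phlda3 at 0.57 and Plk2 at 0.55. The hypoxia list had 2 of 21 higher and 1 lower, and 1 and 0 adjusted over the list alone (camera adjusted p = 0.777), with P4ha1 at 1.38, Ndrg1 at -0.49 and Hk2 at 0.47. The interferon list had 1 of 26 higher and 4 lower, and 1 and 3 adjusted over the list alone (camera adjusted p = 0.0857), with Cxcl10 at 1.37 and Rsad2 at -1.21. Immediate early genes had 3 of 20 higher and 2 lower, and 3 and 2 adjusted over the list alone (camera adjusted p = 0.481), with Hspa1b at -0.81, Atf3 at -0.78, Egr2 at 0.69 and Egr1 at 0.65.

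By tumour these ratios are given as values, since differences of lists among tumours were not tested. The mean log2 ratio of the epithelial list was -4.83 ± 1.61 (SD, n = 8 tumours) and ran from -6.65 in tumour K2 to -2.47 in tumour E1. That of the mesenchymal list was 2.32 ± 1.14. In tumour E5 the mesenchymal list stood at -0.03, the fibroblast list at -0.54, the pericyte list at 0.14 and the EMT factors at 0.06, whereas the mesenchymal list of the other tumours lay between 2.14 and 4.10. The basal list was 0.78 in tumour K5 and between -3.71 and -0.56 elsewhere.

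**Figure D2:**
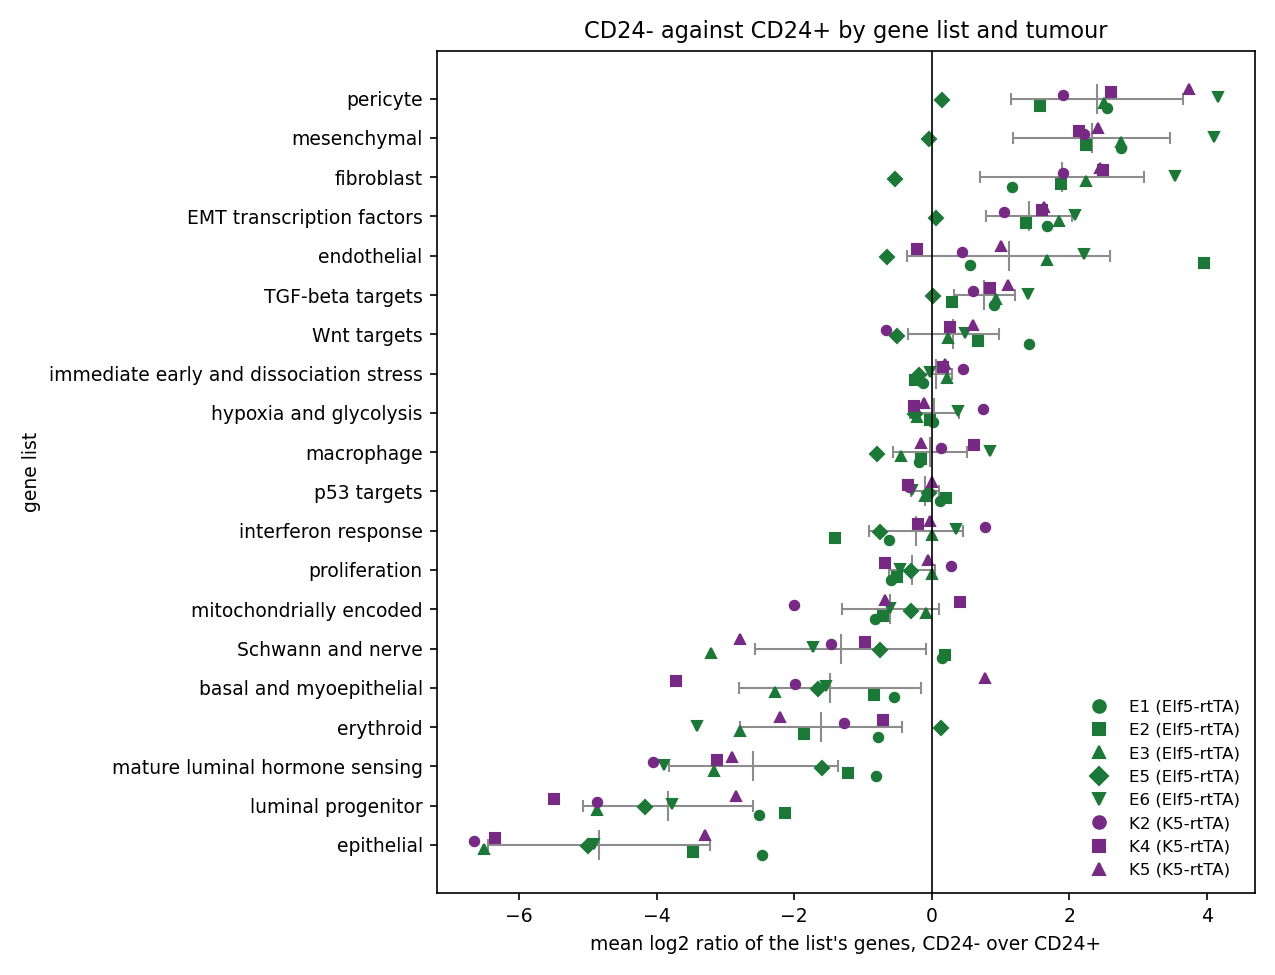
Mean log2 ratio of CD24- to CD24+ CPM over the members of each gene list (horizontal axis) in each tumour, with green points for Elf5-rtTA and purple points for K5-rtTA tumours and a grey bar for the mean and SD of the 8 tumours. The epithelial list lies between -6.65 and -2.47 and the mesenchymal list has 1 tumour, E5, at -0.03.

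With tumour as a block, edgeR called 2408 genes higher and 2048 lower in CD24- cells among 15389 tested, and 2609 of the called genes had the same direction in all 8 tumours. Of the 20 lists tested 11 passed camera, 0 with an estimated correlation, and 9 passed fry, which asks whether a list's genes move one way. Without the pairing of fractions within tumours the count was 878, without tumour E3 it was 2933, and with clones weighted equally it was 2541, of which 34.2% were higher against 54.0%, the median of all genes having moved by -0.42. No gene named for this comparison changed direction in those settings. With clones as blocks 3363 genes were called, 43.7% of them higher. Since the sums weight clones by depth, and differently in the CD24 fractions, the balance of directions may in part reflect clone composition. Equal weights in turn count the 4 CD24- libraries under 2000000 counts like deep ones, and genes without reads there sit at the floor. Which of these shifts the balance was not tested.

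Exon counts asked whether the same genes were spliced differently in the CD24 fractions. The CD24- cells used less of a long exon of Tacc2, a centrosome-associated protein (exon 3, chr7:130621721-130626841, coding). It held 3.51% of the gene's reads against 27.72% in CD24+ cells (log exon ratio relative to the gene -1.78, adjusted p = 4.0e-05, lower in 8 of 8 tumours). The log exon ratios here and for the splicing list are natural logs, as the exon test returned them. An alternative exon of the spectrin Sptbn1 (exon 2, chr11:30197724-30198257, coding and UTR) held 0.10% against 0.80% (-2.20, adjusted p = 9.4e-14, 8 of 8). Exon 2 of Lima1, an actin-binding protein (chr15:99843675-99843823, coding and UTR), was at -1.88 (adjusted p = 1.3e-06), exon 7 of the ubiquitin ligase Trim7 (chr11:48849478-48850195, coding and UTR) at -1.99 and exon 25 of ankyrin-G, Ank3 (chr10:69925532-69926191, coding and UTR), at -2.07, each lower in 8 of 8 tumours.

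The list of 25 exon targets of epithelial splicing regulators had 24 genes tested, of which 3 were called and 4 adjusted over the list alone. Exon 9 of Numb, a Notch inhibitor (chr12:83797197-83797343, coding), held 0.81% of reads in CD24- and 5.33% in CD24+ cells (-1.84, adjusted p = 4.6e-05, lower in 7 of 8 tumours). Exon 13 of the kinase gene Slk (chr19:47627648-47627740, coding) held 0.28% against 0.77% (-1.59, adjusted p = 0.00417, 6 of 8). In Epb41l5, a polarity gene, the last exon (exon 26, chr1:119545033-119549195, coding and UTR) held 56.80% against 9.50% (1.66, gene adjusted p = 0.045, exon adjusted p = 0.0721, higher in 8 of 8). Of the list's genes, 3 also stand on another list. In all, edgeR's diffSpliceDGE with a Simes test called 18 of 10747 genes from 77605 exons, and 17 single exons. The count was 11 without tumour E2 or K5, 10 without E3, E6 or K4, 11 with clones as blocks and 39 with limma's diffSplice. Whether the counting used strand is not given in the sources used here, so reads from an overlapping gene cannot be told apart.

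Tumours with several clones allowed the same contrast within a tumour, with each clone giving a CD24+ and a CD24- library. The surface antigen Ly6d and the secreted Wfdc18 were among the 3 genes with the smallest p in each K5-rtTA tumour, Ly6d at -7.56 in K4, -5.79 in K5 and -8.22 in K2, and Wfdc18 at -7.29, -6.40 and -7.16. The third gene was the keratin Krt7 in tumour K4 (-7.40), arginase Arg1 in K5 (-5.28) and Pgr in K2 (-9.69). In tumour E3 the genes were Cldn4 (-7.85), Krt7 (-6.71) and the ion transport regulator Fxyd3 (-7.27), and in E6 the anchoring collagen Col7a1 (4.62), Cldn4 (-7.19) and the GABA receptor subunit Gabrp (-9.58). Several of these ratios rest on few CD24- reads, so their size is uncertain. In K2 the RFP clone had 1 read of Pgr and 2 of Ly6d and the other clones 0, and in E6 Gabrp had 2 and 0. The K4 GFP CD24- library, with 15363 counts, had 0 reads of Ly6d, Wfdc18 and Krt7. Cd24a was called lower in all 5 tumours, by log2 ratios of -7.53 in K4, -5.57 in K5, -5.32 in K2, -5.30 in E3 and -6.54 in E6.

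The edgeR model of clones called 184 genes higher and 517 lower in CD24- cells of tumour K4, 106 and 360 in K5, 28 and 115 in K2, 84 and 309 in E3, and 5 and 7 in E6, of 15042 tested. The balance of directions depended on the test: limma-voom called 491 higher and 292 lower in K4, 341 and 434 in K5, 9 and 14 in K2, 322 and 513 in E3, and 243 and 175 in E6. In all 5 tumours the same 1 gene was higher and the same 6 were lower. Chosen after their values were seen, these were the fibrillar collagen Col3a1 (3.66 in K4, 4.31 in K5, 5.10 in K2, 4.69 in E3 and 6.70 in E6), and Cd24a, Gabrp, Prr15l, Cldn4, Fxyd3 and Pgr. The other genes called higher in E6, chosen in the same way, were Col6a3 (5.97), Col10a1 (6.20) and Mxra7 (4.07), besides Col7a1. By edgeR 0 genes were called in opposite directions in any pair of tumours. The counts rested on single clones: K4 gave 129 without RFP, 412 without YFP and 272 without CFP, K5 gave 297 without RFP, 68 without YFP and 69 without CFP, K2 gave 0 without GFP or CFP and 4185 without RFP, and E3 gave 4 without RFP, 4 without YFP and 54 without CFP. Without RFP, K2 sets CD24- libraries of 713734 (GFP) and 790823 counts (CFP) against CD24+ libraries of 16118356 and 18219538. Depth and CD24 state cannot be told apart in those 4185 calls. For E6, whose spread is estimated from all tumours, they ran from 0, without K2 CFP or any E3 clone, to 68 without K5 YFP, and for K2 leaving out a clone of another tumour gave 40 to 284. Without clones that have a library under 2000000 counts, E3 gave 0, E6 gave 1 and K4 gave 1195 (551 higher, 644 lower).

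The comparison of drivers asked whether tumours begun from Krt5-expressing and from Elf5-expressing cells differed, first in CD24+ cells. The zinc finger gene Zfp52 (chr17:21535539-21562601) stood at 74.7 ± 12.5 CPM (SD, n = 3 tumours) in K5-rtTA and 10.9 ± 4.20 (n = 5) in Elf5-rtTA tumours, a log2 ratio of 2.73 (SE 0.34), and Enho, the gene of the secreted peptide adropin (chr4:41638144-41640302), had a ratio of 2.77 (SE 0.39). The sodium channel gene Scn5a (chr9:119483408-119579016) had a ratio of -3.64 (SE 0.52). None passed the test, each with an adjusted p of 0.0794. The gene of the driver Elf5 had a log2 ratio of -2.11, Krt5 -0.17, Cd24a 1.24, Pten 0.30 and Trp53 0.53, none called.

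Of 23 lists tested in CD24+ cells, camera called the mitochondrially encoded genes higher in K5-rtTA tumours (0 of 13 called over all genes and 6 adjusted over the list alone, camera adjusted p = 0.00159), with COX3 at 2.83 and CYTB at 1.44, and the mature luminal genes higher (0 of 13 over all genes and 0 adjusted over the list alone, 12 of 13 positive, camera adjusted p = 0.0316), with Prlr at 1.32 and the growth factor Areg at 1.31. Both had adjusted p = 0.916 with an estimated correlation. Adjusted over the list alone, 3 hypoxia genes were higher, Bnip3 (2.71), Ankrd37 (2.55) and adrenomedullin, Adm (2.17), with the fibroblast genes Lum (5.70) and Mfap5 (3.05), and 1 luminal progenitor gene, Wfdc18 (3.03). The p53 target Tnfrsf10b (-1.85), the immediate early gene Egr2 (-1.74) and the endothelial receptor gene Kdr (-4.00) were lower adjusted over the list alone, and of 3 T and NK cell genes Gzma (3.44) and Lck (2.14) were higher and Cd3e (-6.82) lower. Kdr and these 3 were named after their values were seen. The other lists had 0 members called over all genes or adjusted over the list alone by edgeR.

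Across 16405 genes edgeR called 0 between drivers in CD24+ cells, with 4284 at an unadjusted p under 0.05 where chance gives 820, while DESeq2 called 2668, and limma-voom with single libraries as replicates and tumour as a random block called 2274. Without tumour K2 edgeR called 5847 (2778 higher in K5-rtTA), without K5 it called 2 and without clones with a library under 2000000 counts 1022. The CD24+ sum of K2 correlated with those of K4 and K5 at 0.814 and 0.835 and with the Elf5-rtTA tumours at 0.874 to 0.936. Sequencing date and driver overlapped: K4 and K5 came on dates of their own apart from 1 library, and with date as a block edgeR called 0 (1199 at an unadjusted p under 0.05). All but 1 of the libraries of K4 and K5 also had the highest share of gene counts falling in listed exons, 73.6 to 87.7% in 15 libraries, against 53.5 to 71.5% in K2 and 48.1 to 58.7% in Elf5-rtTA tumours. K4 GFP CD24-, sequenced on the later date, had 63.0% (exact 95% interval 62.2 to 63.8).

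In CD24- cells edgeR called single genes between drivers, but 0 genes with date as a block, 0 without tumour E1, E2, E3, E6 or K4, 1 without K5 and 2 without E5. Foxg1 (chr12:49382883-49386867), a transcription factor of the embryonic forebrain, stood at 81.4 ± 70.3 CPM (SD, n = 3) in K5-rtTA tumours and 0.0235 ± 0.0208 (n = 5) in Elf5-rtTA tumours, with 5615 and 5 reads, a log2 ratio of 11.65 (SE 0.999, adjusted p = 0.0124). The histone genes H2ac24 (7.22, chr13:21833083-21833475) and H2ac23 (7.20, chr13:21810367-21810880), near-identical copies whose reads cannot be separated, were higher, as were the matrix protein Thbs4 (6.80, chr13:92751586-92794818) and Apoo (6.01, chrX:94367110-94417093), a mitochondrial membrane protein. The PIWI protein Piwil2 (5.33), the secreted Angptl1 (5.20) and neuritin, Nrn1 (4.75), were higher too. Lower in K5-rtTA tumours were the collagen receptor subunit Itga2 (-4.92, chr13:114835912-114932041), Scn5a (-4.09), the kinase inhibitor Camk2n1 (-3.24), the adhesion receptor Adgre5 (-3.23), complexin Cplx2 (-3.08), the flippase Atp9a (-3.07), the semaphorin receptor Plxnb1 (-3.05) and teneurin Tenm4 (-2.95). Their adjusted p-values ran from 0.0124 to 0.0490. Several of these genes were uneven among the 3 K5-rtTA tumours: H2ac24 had a log2 CPM of 5.55 in K4 and 5.61 in K5 but -0.62 in K2, and Apoo 5.60 and 5.24 but -0.17, whereas Thbs4 reached 10.55 in K2 and Foxg1 had 6.37 in K2, 7.24 in K4 and 3.42 in K5. The genes Elf5 (-2.51), Krt5 (0.88), Pten (0.88), Cd24a (0.86) and Trp53 (-0.18) were not called.

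**Figure D3:**
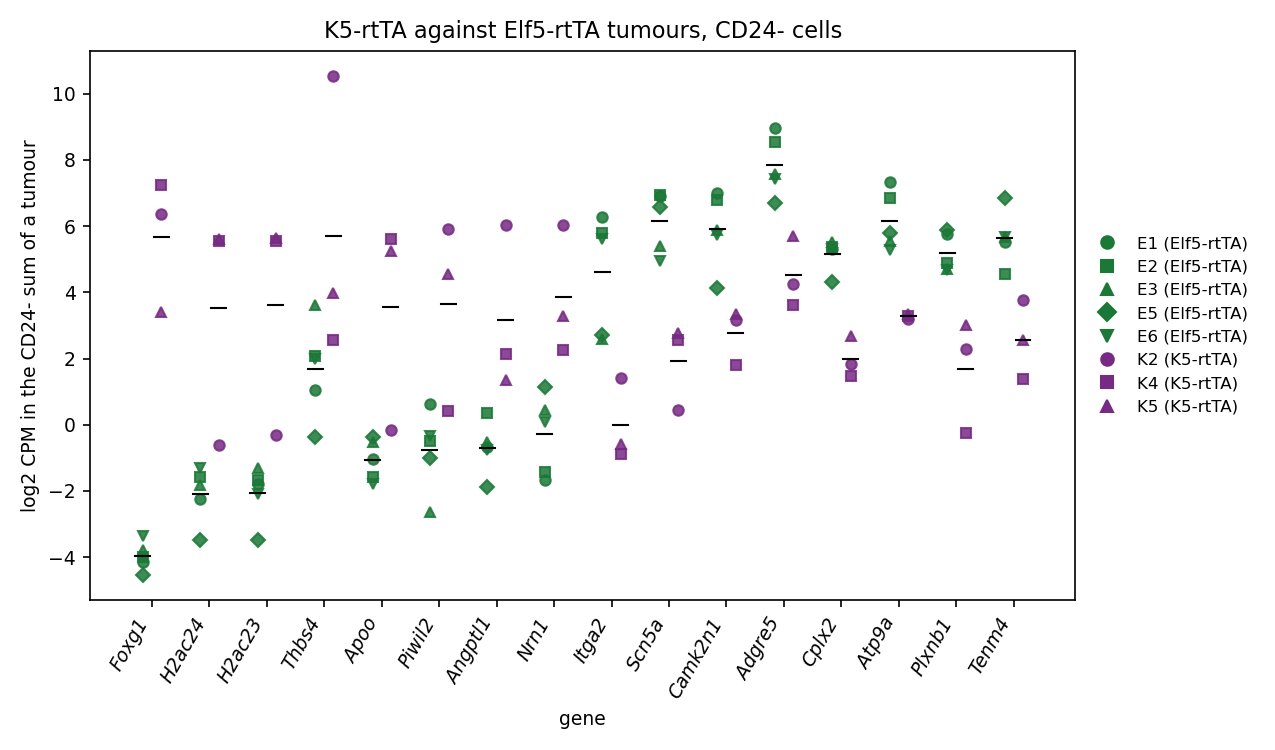
Log2 CPM in the CD24- cells of each tumour (points, green Elf5-rtTA, purple K5-rtTA) for the 8 genes most raised and the 8 most lowered between drivers, with a black line at each group mean. Foxg1 lies at 3.42 to 7.24 in the K5-rtTA tumours, and the K2 point of H2ac24 and Apoo lies at -0.62 and -0.17.

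Of 22 lists tested in CD24- cells, camera called hypoxia genes higher in K5-rtTA tumours (3 of 21 called over all genes and 6 adjusted over the list alone, adjusted p = 0.0339), with the mitophagy gene Bnip3 (2.61), Ankrd37 (2.54) and the glycolytic enzyme Pgk1 (1.35), together with fibroblast genes (0 of 10 over all genes and 2 adjusted over the list alone, adjusted p = 0.0339) and interferon genes (0 of 26 and 0 adjusted over the list alone, 22 positive, adjusted p = 0.0408). All 3 had adjusted p = 0.925 with an estimated correlation. Of the EMT factors 1, Foxc2 (2.56), was higher, and adjusted over the list alone 1 was higher and 1 lower. Of the proliferation genes 3 were higher, and 3 adjusted over the list alone, Ccnb1 (1.75), Birc5 (1.45) and Tyms (1.37), the last of which stood at -0.42 with clones weighted equally. Of the mitochondrially encoded genes 1 was higher, and 1 adjusted over the list alone, COX3 (3.44, chrM:8607-9390), at a log2 CPM of 14.59 in K4, 13.26 in K5, 10.27 in K2 and 9.59 to 10.69 in the Elf5-rtTA tumours. The other lists had 0 members called over all genes or adjusted over the list alone by edgeR.

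Across 15818 genes edgeR called 703 higher and 192 lower in K5-rtTA CD24- cells. Without tumour E1, E2, E3, E6 or K4 the count was 0, without K5 it was 1, without E5 2 and without K2 4491, which included 888 of the 895. With date as a block it was 0 (3170 at an unadjusted p under 0.05), with clones weighted equally 2237, of which 44 were higher with a median shift of -1.26, with limma-voom on single libraries as replicates and tumour as a random block 1695 (470 higher, shift -0.31), with DESeq2 3447, with exon counts 1546 and with no filter 474. With that block the driver rests on the date shared by tumours K2, E1 and E2, so batch and driver cannot be told apart for the other tumours.

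Whether the CD24 effect differed between drivers or tumours was tested directly. The mediator kinase gene Cdk19 (chr10:40349308-40483818) had a ratio of CD24- to CD24+ that was lower in K5-rtTA tumours by -1.73 on the log2 scale (SE 0.22), with the DNA polymerase gene Rev3l (chr10:39732160-39875206) at -1.71 (SE 0.23) and the ion cotransporter Slc12a2 (chr18:57878678-57946821) at -2.24 (SE 0.35, adjusted p = 0.384). None was called. The genes Cd24a (-0.79), Trp53 (-0.77), Krt5 (-0.80), Pten (0.03) and Elf5 (-0.60) were not called either. Over 15389 genes edgeR called 0 with 1160 at an unadjusted p under 0.05 (chance gives 769) and a smallest adjusted p of 0.256, while DESeq2 called 131. Lists had not been planned for this difference and their tests were added. Of 20 lists camera called 5, all with adjusted p = 0.941 with an estimated correlation, and fry called 0. The CD24- to CD24+ ratio was higher in K5-rtTA tumours for interferon genes (25 of 26 positive, median 0.69, camera adjusted p = 2.9e-05), immediate early genes (16 of 20, 0.40, 0.000724) and proliferation genes (21 of 28, 0.25, 0.0481). It was lower for epithelial genes (31 of 36 negative, median -0.98, camera adjusted p = 0.0209) and mature luminal genes (11 of 12, -0.99, 0.0481). By edgeR 0 members of any list were called over all genes, and adjusted over the list alone 1 immediate early gene was higher, Egr2 (0.99). Among the 8 tumours the spread was taken from the clones of the 5 tumours that had several. There edgeR called 0 genes whose CD24 effect differed, with 157 at an unadjusted p under 0.05 (chance gives 752), and limma-voom 0. Of simulated differences among tumours, 0 of 100 genes changed 4-fold and 21 of 100 changed 16-fold were recovered. The 0 calls therefore do not show that the CD24 effect was alike among tumours. The smallest unadjusted p, from 0.000217 to 0.00155, belonged to the protease inhibitor Slpi, Areg, the collagen Col2a1, the adhesion gene Chl1, the cysteine dioxygenase Cdo1 and the tricellular junction gene Lsr. With no filter on low counts that test called 107 genes.

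The colours asked whether clones of 1 tumour differed from each other in both fractions. In tumour K5 edgeR called the basal keratin Krt17 (chr11:100256217-100260989) among clones (adjusted p = 0.0330, but 0.298 without clones that have a library under 2000000 counts), at 754 and 526 CPM in the CD24+ and CD24- cells of the GFP clone, 13.7 and 0 in RFP, 20.2 and 7.22 in YFP, and 111 and 6.92 in CFP. Krt14 had a like profile, 2620 and 1580 in GFP but 49.1 and 1.59 in RFP, and it missed the threshold (adjusted p = 0.114), as did Slpi (0.0989). In tumour K2 the genes called depended on the scaling, with 0 called by RLE. They were Evi2a (chr11:79526560-79530609), a membrane protein gene, at 29.5 and 40.5 CPM in RFP against 0 and 0 in GFP (adjusted p = 0.0297, 0.0695 with RLE), and the semaphorin receptor Nrp2 (chr1:62703317-62818692), at 293 and 285 in RFP against 16.8 and 46.3 in GFP (adjusted p = 0.0297, 0.076 with RLE), while Nsg1 missed the threshold (adjusted p = 0.05003). In tumour K4 the X-linked Xlr4a (chrX:73074345-73082507) was at 105 and 98.9 CPM in YFP, 0 and 0 in RFP and CFP, and 75.8 and 0 in GFP, whose CD24- library had 15363 counts in total, but it was not called (adjusted p = 0.178), nor were Col2a1 (0.279) and the corepressor Tle4 (0.358). Xlr4a has close copies. The 3 genes with the smallest p were Steap4, Cldn4 and Il33 in tumour E3 and Pgr, Krt19 and Ace in E6, with an adjusted p of 1 each.

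**Figure D4:**
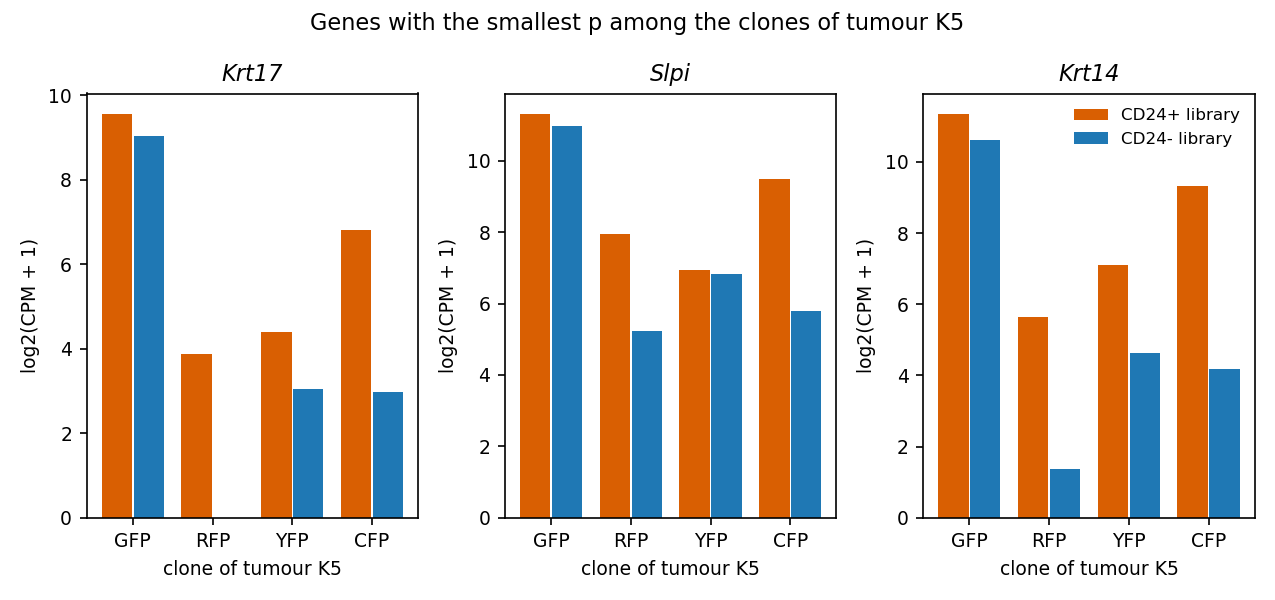
Log2 of CPM plus 1 in the CD24+ (orange) and CD24- (blue) library of each clone of tumour K5 for Krt17, Slpi and Krt14, 1 library per bar. Krt17 in the GFP clone stood at 754 and 526 CPM.

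The edgeR model called 1 gene among the clones of K5, 2 in K2 and 0 in each of K4, E3 and E6. In that order 693, 2196, 1059, 56 and 66 genes had an unadjusted p under 0.05, where chance gives 752, so K5, E3 and E6 lay below chance. Of simulated differences among K5 clones, 5 of 100 genes changed 4-fold and 47 of 100 changed 16-fold were recovered. The few calls therefore do not show that clones were alike. Limma-voom called 46 in K4, 155 in K2, which included both genes called by edgeR, and 1 in K5, which was not Krt17 (limma-voom adjusted p = 0.059). With RLE scaling K5 gave 1 and K2 0, without clones that have such shallow libraries K5 gave 0, and with no filter on low counts K4 gave 185, K5 286, K2 793, E3 4 and E6 0. The K5 count was 0 without K4 GFP or CFP, K5 GFP or RFP, any K2 clone, or E3 RFP or CFP, and 2 without K5 YFP or CFP or either E6 clone. The K2 count was 0 without K4 CFP, K5 RFP or CFP, K2 RFP or CFP, or any E3 clone, and it was 5 without K4 GFP, 6 without K4 RFP, 51 without K4 YFP, 45 without K5 GFP, 22 without K5 YFP and 7 without either E6 clone.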

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

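Of the tests in this part, those of sequencing date, library kit, driver and exon counts for tumour K2, the tests for E1, for E2 and for the other tumours taken apart, the omission of shallow clones, the permutation of chromosome shifts and 36 of the splits of exon usage were chosen after the result was seen. The comparisons, gene lists, naming rule, other splits and all alternatives except exon counts summed per gene and the omission of shallow clones were fixed before the data were examined. Each value below stood far from the others of its group in a range-based test, and chance puts about 1 in 20 groups on such a list. The 111 groups gave 10, and 0 of them came from the 60 sets of CD24 ratios of lists and genes.

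The CD24+ cells of tumour K5 had a Trp53 floxed-exon density of 5.60% of the flanking exons against 0.00 to 1.34% in the other tumours, carried by the CFP clone with 33 of the 39 reads (21.96%), while the RFP and YFP clones had 0 reads there. In CD24+ cells of tumour E3 the Pten figure was 2.43% against 0.00 to 0.95%, resting on 1 read. The CD24- cells of tumour E2 had 13.47% for Pten against 0.00 to 2.36%. Among the Elf5-rtTA tumours E5 stood apart in the log2 CPM of Pten in CD24+ cells (8.04 against 5.66 to 6.35), and in CD24- cells of Trp53 (4.55 against 1.65 to 2.42), Elf5 (-2.47 against 0.62 to 1.65) and Cplx2 (4.32 against 5.30 to 5.53). The CD24- library of E5 had 3.41% of counts on the mitochondrial chromosome against 0.26 to 1.75% in the other Elf5-rtTA CD24- libraries. In the CD24- libraries of tumour K4, Xlr4a stood at 6.61 in the YFP clone and Col2a1 at 4.95, with the other clones at -3.21 for each gene, the floor of 0 reads. For GFP, with 15363 counts in total, that floor says little, and its CD24+ library had Xlr4a at 75.8 CPM (1000 reads, against 105 in YFP) and Col2a1 at 143 (1886 reads, against 298), so YFP was not alone in CD24+ cells.

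The genes higher in CD24- cells include fibroblast and pericyte markers, so unrecombined stromal cells may have entered that fraction, although the Confetti gate would remove them. Such cells keep Trp53 exons 2 to 10 and Pten exon 5, and to lift the genes as far as seen they would need between 3.6% (E5) and 36.8% (E6) of the reads. In 7 of the 7 tumours other than E2 the upper 95% bound of the Pten or the Trp53 density lay below the share needed. Apart from E5, this argues against such cells as the whole source there, provided that stromal RNA holds about as much Pten and Trp53 (by Pten alone, the form set first, the bound lay below in 6 of 8, E5 being the other exception). In E5 just the Trp53 bound lay below, 0.52 against 3.6%. Its CD24- cells had a Trp53 log2 CPM of 4.55, against 1.65 to 2.42 in the other Elf5-rtTA tumours. The proviso is therefore in doubt in E5, where stromal cells stay open. The mesenchymal, pericyte and fibroblast lists alone need less, and for them 1 bound or both lay below in 6 of the 6 tumours other than E1 and E2, both in E6 and K4 and just 1 in the rest (Trp53 was above in E3, 18.86 against 18.0%, and K5, 7.39 against 6.6%, and Pten in K2, 14.09 against 10.5%, and E5, 7.33 against 1.0%), whereas in E1 the lower of the Pten and Trp53 upper bounds, 5.24%, exceeded the 4.5% needed and stromal cells stay open as their source. In E5 the mesenchymal and fibroblast lists did not rise (-0.03 and -0.54) and the pericyte list hardly did (0.14). The share needed counts just the genes with a gain, so E5 decides nothing for these lists. Its bound also rests on Trp53 alone (0.52 against 1.0%). In tumour E2 the Pten density, 13.47%, and the Trp53 density, 12.18%, reached the 11.7% needed, so stromal cells remain a candidate explanation there, while shallow libraries are argued against as the whole source since 1753 genes were higher without them, against 2408 with them.

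In CD24+ cells tumour K2 stood nearer to the Elf5-rtTA tumours than to K4 and K5, which share its driver. Its correlation there was 0.814 with K4 and 0.835 with K5 but 0.874 to 0.936 with the Elf5-rtTA tumours, and K4 with K5 gave 0.941. Date is argued against, since the mean correlation of K2 with E1 and E2, which share its date, minus its mean with E3, E5 and E6 was at most -0.019 (in CD24+ cells E5, at 0.874, was below E1 at 0.893 and E2 at 0.896), and so is the kit, since K4 was closer to K5 than to any other TruSeq tumour by 0.056 or more. In CD24- cells the correlations of K2 with E1 (0.845) and E2 (0.833) lay under its 0.852 with K4, and those with E3, E5 and E6 lay above. A shared driver would bring K2 near K4 and K5. In CD24+ cells both lay below every Elf5-rtTA tumour (0.835 at most against 0.874 at least), which argues against the labelled driver as the source of its place there. In CD24- cells the margin of 0.019 for E2 leaves the driver open. Exon counts gave a nearly equal margin, 0.018, in the higher of the CD24 states. Since CD24+ cells are not given apart for exon counts, the reads that those counts omit stay open. The earlier dates of K4 and K5 cannot be told apart from a biological difference of those tumours, and a wrong driver label for K2, on which the driver counts rest (in CD24+ cells 0 genes with K2 and 5847 without it), is not excluded either.

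On average over clones the fractions of a clone shared chromosome-wide shifts relative to the other clones of the tumour, as in K4 YFP, where chromosome 13 stood at -0.34 and -0.30 in CD24+ and CD24- cells, and K2 RFP, where chromosome 14 stood at 0.36 and 0.25. The CD24- value of K2 RFP is set against GFP and CFP libraries of just 713734 and 790823 counts. That of K4 YFP is set in part against GFP, with 15363 counts. The mean correlation across chromosomes was 0.405 for the fractions of 1 clone and 0.004 for exchanged fractions (exact permutation p = 0.000217, 9 of 41472 arrangements, one-sided), but own fractions correlated best in just 11 of 16 clones and in 6 of 11 without shallow ones, K4 CFP (0.688 against 0.809), K5 GFP (0.490 against 0.764), K2 CFP, E3 RFP and E3 YFP being the exceptions among the 16. Clones may differ in the dose of whole chromosomes, a hypothesis found and tested on the same data. With the GC trend removed the mean was 0.404, and with the expression trend removed and shallow clones left out it was 0.310 (exact permutation p = 0.0312), which argues against these trends as the whole source. Shared regulation of neighbouring genes was not tested.

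For CD24- against CD24+, 1 of 100 splits of the 8 pairs gave as many genes as the 4456 seen, the real one, and the highest other gave 3491. That split exchanged the fractions of tumour E5 alone and so kept the other 7 pairs in place, and the fractions of E5 had a correlation of 0.967. That share, under 0.05, argues against chance for this count. For the drivers in CD24- cells 1 of 56 splits reached 895, the smallest share possible, and the highest other gave 69, which argues the same way. These splits take no account of date, which overlaps with driver, and the count of 895 was 0 with date as a block (3170 at an unadjusted p under 0.05) and 0 to 2 without any 1 of the 7 tumours other than K2, so date stays open as its source. For exon usage 60 of the 128 splits were run, 24 drawn before a result was seen and 36 added, among them every exchange of a single tumour not drawn before. Of these 60, 1 reached 18, a share under 0.05 that argues against chance, though the highest other, again E5 alone, gave 15. For the drivers in CD24+ cells and for the interaction the real count was 0, which every split reaches by construction (56 of 56 each), so these shares say nothing about chance. The highest splits gave 1658 for E5, K4 and K5 against the rest and 314 for E1, E2 and E5 in the interaction. Just 1 other split in CD24+ cells and 2 in the interaction exceeded the real count of 0, these included. Whether a structure of the samples lies behind them was not tested. Within single tumours the splits are too few for a share under 0.05, with 1 split reaching the count in each: 701 in K4 (highest other 1), 466 in K5 (0), 143 in K2 (0) and 393 in E3 (0).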

How the results depend on the processing

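Exon counts summed per gene and the omission of clones with a library under 2000000 counts were chosen after the data were seen. The cause of each change below was not tested, except that a block on date, the omission of clones or tumours and the omission of the filter change by construction the samples or genes that decide. Of 3598 recomputed values of named genes, 2983 kept their direction and side of the threshold, 512 lost the call, 73 gained it and 30 changed sign. In CD24- against CD24+ 0 of 1697 values changed sign. Counts of genes given here without a tool are by edgeR.

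For CD24- against CD24+ (4456 genes), all alternatives kept both directions. The count was 2541 with clones weighted equally, 878 (353 higher, 525 lower) with no replicate block, that is without pairing, and 2933 to 4869 with each tumour left out. For the drivers in CD24+ cells (0) it was 2668 with DESeq2, 2 with clones weighted equally, 1022 without shallow clones, 620 with exon counts, 2274 with limma-voom on single libraries as replicates (tumour as a random block) and 0 to 5847 with each tumour left out. In CD24- cells (895) it was 3447 with DESeq2, 474 with no filter, 2237 with clones weighted equally, 1546 with exon counts, 0 with date as a block, 1695 with that limma-voom fit and 0 to 4491 with each tumour left out. For the driver difference in the CD24 effect (0) it was 131 with DESeq2 and 0 to 0 with each tumour left out, and for the difference among tumours (0) it was 107 with no filter and 0 to 0 with each clone left out. Clones weighted equally moved the median of all genes by -0.12 in CD24+ and -0.95 in the driver difference, omission of shallow clones by 0.13 and the date block by 0.11 in CD24+, and clones as blocks by -0.27 in the driver difference and -0.19 in CD24- against CD24+.

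Among clones, tumour K4 (0) gave 46 with limma-voom, 185 with no filter and 0 to 0 with each clone left out. Tumour K5 (1) gave 286 with no filter, 0 without shallow clones and 0 to 2 with each clone left out. Tumour K2 (2) gave 0 with RLE, 155 with limma-voom, 793 with no filter and 0 to 51. Tumour E3 (0) gave 4 with no filter and 0 to 0, and E6 (0) gave 0 to 0. For CD24- against CD24+ within tumours, no filter gave 1251 in K4, 1027 in K5, 1293 in K2, 970 in E3 and 585 in E6, against 701, 466, 143, 393 and 12. With limma-voom these were 775 in K5, 23 in K2, 835 in E3 and 418 in E6. Without shallow clones they were 1195 in K4, 0 in E3 and 1 in E6, and with each clone left out 129 to 850, 68 to 604, 0 to 4185, 4 to 553 and 0 to 68. K2 without shallow clones has 1 clone and gave no value. Exon usage (18) gave 39 with diffSplice of limma, 11 with clones as blocks, of which 6 were among the 18, and 10 to 22 with each tumour left out. Of the lists, 11, 2 and 3 passed camera in the CD24, CD24+ and CD24- comparisons, 0, 0 and 0 with an estimated correlation and 9, 0 and 0 with fry.

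No gene below was called except Tyms. Between drivers in CD24+ cells Pten was -0.02 with exon counts, and with each tumour left out Krt5 ran from -0.72 to 0.29 (0.15 without E3 and 0.10 without K2). In CD24- cells, the date block gave -1.55 for Cd24a, 0.32 for Trp53, -4.95 for Krt5 and -0.02 for Pten. Limma-voom on single libraries as replicates gave 0.69 for Trp53 and -0.45 for Krt5, equal weights -0.39 for Krt5 and -0.42 for Tyms. With each tumour left out Cd24a ran from -0.88 (without K5) to 1.34, Krt5 from -4.29 (without K5) to 3.78 and Trp53 from -0.46 to 0.77 (without E5). In the driver difference Krt5 was 0.23 with equal weights, 1.47 with clones as blocks and -2.70 to 1.54 with each tumour left out, positive without K2 (0.27) and K4. Pten there was -0.00 with RLE, -0.00 with DESeq2, -0.37 with equal weights, -0.25 without shallow clones, -0.44 with clones as blocks, and -0.24 (without K4) to 0.45 with each tumour left out, negative also without E2 (-0.03), E5 (-0.23) and K5 (-0.14). Elf5 was 0.29 without shallow clones and ran from -3.93 to 0.76 (without K2). At this depth and number of tumours, simulated 2-fold differences of the CD24 effect between drivers were recovered for 0 of 100 genes.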

Other observations

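The values in this part were chosen after the result was seen.

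The endothelial list had a mean log2 ratio of CD24- to CD24+ of 3.96 in tumour E2, 2.21 in E6 and -0.65 to 1.67 in the others, a difference among tumours that was not tested. Single genes of lists too small to test included the neutrophil gene S100a8, a calcium-binding protein, which fell by 1.35, and the adipocyte lipid carrier Fabp4, which rose by 2.08, both called over all genes. The share of counts on the mitochondrial chromosome ran from 2.73 (GFP CD24-, 15363 counts) to 11.18% in the libraries of tumour K4, 3.77 to 13.05% in K5, 0.81 to 15.60% in K2, and 2.14 to 4.30% in the CD24+ and 0.26 to 3.41% in the CD24- libraries of Elf5-rtTA tumours.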
